A study of Callobius koreanus with 6 samples.

How the data were processed

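RNA from the spider Callobius koreanus was measured in 6 libraries, 3 from venom gland and 3 from the whole body after removal of the venom glands. Per the labels' protocols, the spiders were caught in the wild, the glands were taken out of the chelicerae and rinsed in phosphate-buffered saline, total RNA was isolated with TRIzol, and sequencing was done in triplicate for each tissue. The labels do not say whether the 3 libraries of a tissue came from separate animals, so the p-values below measure only the spread between these libraries, which may be partly technical. Groups and replicate numbers were taken from the sample titles, and 0 columns of per-sample values were left without a sample.

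The authors deposited 1 table per library with an expected count and a TPM for each of 151080 unigenes, the assembled transcripts that stand in for genes here. Per the submitters' processing notes, FastQC 0.10.0, Trimmomatic 0.32, Bowtie and RSEM were used, and no version is given there for Bowtie or RSEM. The deposited expected counts are RSEM estimates per unigene without normalisation. They held no fraction in any library, so rounding them to whole numbers changed none. The deposited TPM values are RSEM's length-corrected relative levels (TPM), per the file headers, and each library had nearly the same sum. Unigenes came from a Trinity assembly per the deposited file names, with a length of 201 to 24016 bases and a median of 326. The deposited peptides are TransDecoder reading frames, per the source column of the deposited annotation. There were 22258 peptides on 21214 unigenes, which is 14.04% of those listed, and the shortest had 99 residues, so shorter toxins were not among them. Of these reading frames 10046 were complete, 4701 were open at the 5' end, 2064 at the 3' end and 5447 at both. Every unigene had 1 transcript, and 28232 had a count in no library. How the aligner placed reads shared between near-identical unigenes is not given in the sources used here, so values of single members of multigene families, toxins included, are uncertain. Positions are 1-based on the unigene, not on a genome. No genome was used here.

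The files do not pair unigenes with gene names. Therefore 46 sequence classes were fixed before the data were examined, from recalled PROSITE-style patterns and composition rules applied to the deposited peptides, and a unigene belonged to a class when any of its peptides matched. The short secreted classes took complete peptides of 40 to 150 residues with a hydrophobic stretch near the N-terminus, meaning 8 residues within residues 2 to 25 with a mean Kyte-Doolittle hydropathy of at least 2.0. Cysteine patterns were then read after residue 20. The agatoxin-type class needed the inhibitor cystine knot pattern with a pair of C-x-C motifs, the other cysteine knot class the knot pattern alone, and the remaining cysteine-rich class at least 6 cysteines. The cationic class needed at most 1 cysteine and a net charge of at least 5. A class name states a pattern match, not a tested function. On shuffled copies of the peptides, in which short classes kept the first 25 residues, agatoxin-type, astacin, Kunitz, CRISP, P450 and homeodomain patterns matched 0, 0, 0, 0, 3 and 0 times against 10, 35, 24, 7, 52 and 40 real peptides. The other cysteine knot pattern matched 7 shuffled against 20 real peptides, phospholipase A2 10 against 16, serpin 9 against 18, G protein-coupled receptor 19 against 39 and Kazal 1 against 1, so these classes hold chance matches. At lower rates other patterns matched too, among them EF-hand with 16 against 141, C2H2 21 against 705, cathepsin 1 against 12, chitinase 1 against 6 and actin 1 against 4. For the classes defined by composition, the shuffle kept the composition and showed nothing. A further 13 signatures were added after abundant unigenes had been seen and serve only to describe those.

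Unigenes were compared with edgeR 4.0.16 (quasi-likelihood test with robust dispersion, TMM factors, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A prior count of 2 entered only the log2 CPM used for the class tests and for correlations between libraries. CPM in the text are scaled with TMM factors unless raw is stated. The SE of a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F. It was derived from the test and not fitted, and it is approximate for very large changes. Classes with at least 3 tested unigenes, 37 in all, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Shares of counts were compared by an exact two-sided permutation test, which with 3 against 3 libraries cannot give a p below 0.10 and treats all 6 libraries as exchangeable. Exchanges within same-numbered pairs would allow 4 splits. A fold against a group with no counts was computed against a floor of 3 counts over the group and is a lower bound. Fold intervals are 95% Poisson intervals of the summed counts and, like the floor, cover counting error only. The named unigenes followed a rule fixed before the data were examined. It took from each class and direction the called unigene with the highest mean CPM, the 10 most abundant unigenes of each tissue, and by identifier the 2 with the largest rise and the 2 with the largest fall among called unigenes with separated groups and a mean of at least 10 CPM. Others are named by class and peptide length.

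Library totals were 13946099, 18441407 and 13597779 counts in venom gland and 13587711, 16207085 and 15841554 in body. No pair of replicates agreed within sampling noise, since the mean chi-square per unigene was 55.42 to 73.99 between venom gland libraries and 102.14 to 321.39 between body libraries. Medians were 1.903 to 2.45 and 4.291 to 7.398, so the means rest largely on a minority of unigenes. Libraries were scaled by their totals only in this check. These values argue against 1 library sequenced 3 times in either tissue, but separate preparations and separate animals were not told apart. The biological coefficient of variation was 33.3% in venom gland and 43.9% in body. Same-numbered libraries of the 2 tissues deviated together from their group means, with correlations across unigenes of 0.201, 0.195 and 0.137 against -0.158 to -0.018 for other pairs. The numbers come from the sample titles, which do not say what they share. Deviations from a group mean cancel out within each tissue, so the lower values of other pairs partly follow from those of same-numbered pairs. By this check alone the numbers may pair the samples, which it does not settle. A fit with the replicate number as a block was run beside the unblocked one.

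The test was run on simulated data for the venom gland against body comparison with 18596 unigenes. It recovered 71 of 100 unigenes seeded with a log2 change of 3 and 1 of 100 seeded with a log2 change of 1, with 5 false calls, 6.49% of calls, and a median absolute error of 0.41 and 0.28 log2 units. The class test recovered 10 of 10 sets of 20 unigenes shifted by 1.5 log2 units and called 0 of 30 unshifted sets. Unigenes were drawn independently, so the simulation cannot show how the class test behaves when members of a class vary together. Only 100 unigenes were seeded at each size, with equal numbers up and down. It therefore does not cover changes as widespread as those found below. Alternatives were DESeq2 1.42.0, median-of-ratios factors, library totals without composition factors, TMM factors without the 20 most abundant unigenes of each library, no low-count filter, a filter of 1 CPM in 3 libraries, limma-voom, unrounded counts, the replicate block, a 2-fold threshold, unigenes with a reading frame only, other class assignments, TPM in place of counts, and leaving out each library in turn. The figures and the class and permutation steps used Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9.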

Results

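Expression profiles of the venom gland of Callobius koreanus were set against those of the rest of the body, to find which transcripts the gland makes at a higher or lower level. The data are 6 RNA-seq libraries, 3 per tissue. Counts totalled 13587711 to 18441407 per library. Of 151080 assembled unigenes, 46883, 50412 and 46525 had a count in the venom gland libraries and 67003, 70848 and 60886 in the body libraries.

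Venom gland libraries were dominated by a few transcripts that were almost uncounted in the body. The most abundant encodes a 281-residue protein of the trypsin-like class (frame at bases 255 to 1100 of a 1192-base unigene), which took 18.0%, 15.3% and 12.9% of all counts in the 3 venom gland libraries. It stood at 222100 ± 36570 CPM in venom gland and 4.97 ± 2.69 CPM in body (SD, n = 3 each). Trypsin-like proteases use a catalytic histidine and serine. This protein matched the pattern around the histidine but not that around the serine, as held for 19 of the 75 unigenes of its class, itself included. Short cysteine-rich peptides of the kind that includes spider neurotoxins followed. A 108-residue cysteine-rich peptide reached 66910 ± 3997 CPM against 1.62 ± 1.32, a 103-residue cysteine knot peptide 41670 ± 11900 against 0.776 ± 0.530, and a 99-residue agatoxin-type knot peptide 39590 ± 7674 against 0.860 ± 0.568. Without body library 1 the body means of the 108-residue and agatoxin-type peptides were 0.906 and 0.570 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, log2 fold changes were 15.45 (SE 0.86, adjusted p = 2.45e-05) for the protease, 15.34 (SE 1.00, adjusted p = 3.57e-05) for the 108-residue peptide, 15.71 (SE 0.93, adjusted p = 2.78e-05) for the 103-residue peptide and 15.49 (SE 0.85, adjusted p = 2.42e-05) for the agatoxin-type peptide. Those of the 108-residue and agatoxin-type peptides were 16.18 and 16.08 without body library 1. By summed counts the protease and the 108-, 103- and 99-residue peptides were 45980-, 44420-, 57360- and 48960-fold higher. The body level of each was highest in body library 1 and lowest in body library 3. Whether these few body counts came from the body, or from gland RNA or reads carried over, was not tested. The folds may therefore not measure expression in the body.

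The predicted precursors of these 3 peptides are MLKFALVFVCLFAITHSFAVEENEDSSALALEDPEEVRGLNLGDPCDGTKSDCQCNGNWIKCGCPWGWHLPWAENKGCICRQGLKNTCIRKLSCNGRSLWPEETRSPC for the 108-residue peptide (bases 74 to 400, reverse strand, of a 671-base unigene), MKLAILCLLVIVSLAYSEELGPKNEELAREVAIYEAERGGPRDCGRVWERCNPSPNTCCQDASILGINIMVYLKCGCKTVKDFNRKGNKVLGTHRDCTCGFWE for the 103-residue peptide (bases 203 to 514 of a 760-base unigene) and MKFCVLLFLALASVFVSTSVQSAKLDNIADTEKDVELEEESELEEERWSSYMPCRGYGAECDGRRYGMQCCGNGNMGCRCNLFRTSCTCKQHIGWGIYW for the agatoxin-type peptide (bases 363 to 662 of a 768-base unigene). Another of the 10 most abundant venom gland unigenes carried a 148-residue frame open at its 5' end, at 67290 ± 20210 CPM against 1.09 ± 0.557 in body. It met the rules of the short cysteine-rich classes when read from a methionine inside the frame, an assignment made after its level had been seen. A complete 172-residue frame in no class stood at 42510 ± 13590 CPM against 15.3 ± 16.6, or 5.71 without body library 1. A further 3 of the 10, without a predicted peptide, stood at 44730, 25880 and 25780 CPM and below 1 CPM in body.

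Single larger proteins of families found in venoms also rose, each the most abundant riser of its class, while the CRISP, serpin and peptidase classes below were not called. A 424-residue protein of the CRISP family, cysteine-rich secretory proteins common in venoms, stood at 15390 ± 3478 CPM in venom gland and 4.87 ± 0.807 in body (log2 fold change 11.62, SE 0.48). The only hyaluronidase, an enzyme that cuts hyaluronan and helps venom to spread, stood at 321.7 ± 16.1 against 1.43 ± 1.13 CPM, or 0.776 without body library 3 (log2 fold change 7.80, SE 0.61, and 8.66 without that library). Peptidases of the angiotensin-converting enzyme and neprilysin types had members at 1059 ± 123 against 186.5 ± 52.2 CPM and 98.4 ± 22.5 against 4.66 ± 0.963 CPM. A 640-residue protein of the serpin class, named for serine protease inhibitors, rose by 3.01 (SE 0.36) on the log2 scale. The serpin pattern matched 9 shuffled against 18 real peptides, so this name may be a chance match. Adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 1.46e-05 for the CRISP, 6.83e-05 for the hyaluronidase, 3.59e-04 for the angiotensin-converting enzyme-like peptidase, 4.45e-05 for the neprilysin-like peptidase and 3.09e-04 for the serpin.

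Body libraries held transcripts of digestive, silk-like and detoxification classes that were scarce in the gland. A 331-residue cathepsin L/B-like protease stood at 14560 ± 7122 CPM in body and 11.4 ± 19.1 in venom gland, and a 285-residue astacin-like metalloprotease at 5680 ± 1204 against 17.2 ± 26.1. Both families are digestive enzymes in spiders. Without venom gland library 3 these venom gland means became 0.401 and 2.22 CPM. A 171-residue fragment belonged to the spidroin-like class, which is named for silk proteins and defined by composition alone. It need not be a silk protein. The fragment stood at 1766 ± 186 CPM in body with 4 counts in all venom gland libraries together, 13980-fold lower (95% counting interval 5459 to 51300). A 403-residue lipase fell by 8.02 (SE 0.86) on the log2 scale, with a log2 fold change of -9.40 without venom gland library 3, and a 540-residue cytochrome P450, a class of oxidative enzymes that handle foreign compounds, fell by 4.06 (SE 0.47). A 129-residue unigene with a fatty acid-binding signature stood at 11160 ± 2495 CPM against 6.56 ± 9.68, and a 159-residue DM9 repeat protein at 7608 ± 2273 against 5.75 ± 9.32, and the venom gland means of this pair became 0.974 and 0.374 without library 3. Adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.00278 for the cathepsin, 0.00205 for the astacin, 1.89e-05 for the spidroin, 2.08e-04 for the lipase, 2.74e-04 for the P450, 5.80e-04 for the fatty acid-binding unigene and 0.00138 for the DM9 protein. With no low-count filter the adjusted p became 0.129 for the cathepsin, 0.107 for the astacin and 0.0834 for the DM9 protein. The most abundant body unigene, of 7184 bases with a 121-residue frame in no class, took 16.4%, 6.85% and 2.07% of counts in the 3 body libraries and had a log2 fold change of -3.69 (SE 0.74; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00301, and 0.0965 with no low-count filter). Without body library 1 the log2 fold change was -2.66. This unigene was not identified, and ribosomal RNA was not ruled out, so its share and the body totals that include it are uncertain in meaning.

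Over all unigenes, 5030 were higher and 6750 lower in venom gland among 18596 tested, 63.3% of them, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05. An unadjusted p under 0.05 was reached by 12490. Changes were large. With the 94 called unigenes without body counts and the 974 without venom gland counts set at their bounds, 2246 of the higher and 3052 of the lower unigenes differed at least 8-fold, and 62 and 113 at least 1024-fold (80 and 381 by fitted values). The groups did not overlap for 13254 unigenes, 71.3% of those tested, where chance gives 10% if all 6 libraries can be exchanged. Exchanges within same-numbered pairs allow 4 splits, for a smallest share of 25%. Ranked by fitted log2 fold change, which at 0 counts is not a measured fold, the 2 with the largest rise (17.98 and 17.31) were c7268_g1 and c69408_g1. The first, a 109-residue cysteine-rich peptide, stood at 232, 5645 and 169 CPM in the 3 venom gland libraries with 0 counts in body (at least 48430-fold higher). The second, c69408_g1, has no predicted peptide and stood at 1352, 7404 and 2526 CPM with 1 count in body (258100-fold higher, 95% counting interval 46320 to 10190000). The bound of the first lies below the 124800-fold of the unigene without a peptide at 44730 CPM. The 2 with the largest fall by the same ranking, c55867_g1, without a peptide, and c63396_g1, with a 109-residue peptide in no class, had 0 venom gland counts and 866.6 ± 292 and 764.6 ± 371 CPM in body, at least 8977-fold and 8082-fold lower. Without venom gland library 2 the rise of c7268_g1 became at least 4342-fold and that of c69408_g1 125100-fold. Without body library 2 they became at least 30460-fold and 162300-fold, without body library 3 at least 31440-fold and at least 55850-fold, and without venom gland library 2 the falls became at least 5613-fold and 5053-fold. The call on c7268_g1, whose level rests on venom gland library 2, was lost with no low-count filter (edgeR, Benjamini-Hochberg adjusted p = 0.297). Scaling set the balance of directions. Higher calls were 42.7% of all calls with TMM factors and 22.8% with library totals alone, which gave 3179 higher and 10748 lower and shifted log2 fold changes by a median of -1.03, from a median of -0.35 to -1.39.

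Of the 4 classes of short secreted peptides 1 was called higher and the others lower with camera's preset correlation. The 3 that fell are defined by composition or by a pattern that also matched shuffled peptides. Their members need not be toxins, and their falls do not show that toxin families are lower in the gland. No predicted peptide had fewer than 99 residues, so shorter toxins are missing from the numbers higher and lower in all 4 classes. Agatoxin-type knot peptides rose as a class, with 6 of 8 tested members higher and 1 lower and a median log2 fold change of 15.25. Whether the low body counts behind that median came from the body was not tested. The member that fell, of 100 residues, stood at 371.7 ± 82.9 CPM in body and 37.0 ± 8.74 in venom gland. Of 15 other cysteine knot peptides 1 rose, the abundant 103-residue peptide above, and 14 fell. Of 72 other short cysteine-rich peptides 12 rose and 52 fell, and a 100-residue member stood at 3113 ± 1474 CPM in body against 21.3 ± 34.9, or 1.12 without venom gland library 3 (log2 fold change -7.20, SE 1.8, and -11.44 and -6.59 without venom gland library 3 or 2), a call lost with no low-count filter (edgeR, Benjamini-Hochberg adjusted p = 0.223). Short cationic peptides poor in cysteine had 1 of 21 higher and 15 lower. Camera, with Benjamini-Hochberg adjustment over 37 classes, gave adjusted p = 4.63e-04 for the agatoxin-type rise and 0.00123, 1.94e-04 and 0.00666 for the 3 falls. With an estimated correlation each of the 4 had adjusted p = 0.201. With library totals alone the numbers higher and lower were 6 and 1, 1 and 14, 8 and 58, and 0 and 18.

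In 3 protease classes and 1 class of inhibitors more tested members fell than rose. Trypsin-like proteases had 4 of 44 tested members higher and 32 lower, so that the class fell although it held the most abundant venom gland transcript; a 278-residue member stood at 1069 ± 372 CPM in body and 2.42 ± 3.94 in venom gland, or 0.149 without venom gland library 3, a call lost with no low-count filter (edgeR, Benjamini-Hochberg adjusted p = 0.0971). Astacin-like metalloproteases had 1 of 25 higher and 23 lower, cathepsin-like proteases 0 of 12 higher and 8 lower, and Kunitz-type inhibitors 2 of 19 higher and 11 lower. A 787-residue Kunitz-type protein stood at 67.5 ± 32.4 CPM against 0.812 ± 0.475 and a 320-residue one at 0.562 ± 0.673, or 0.176 without venom gland library 3, against 258.5 ± 156. Median log2 fold changes were -4.24 for trypsin-like, -4.97 for cathepsin-like, -8.14 for astacin-like and -8.22 for Kunitz-type unigenes, and the last pair were -7.41 and -5.04 with members lacking counts in 1 tissue set at their bound. Camera gave adjusted p = 1.94e-04, 0.0118, 3.87e-06 and 0.0126 in that order of trypsin, cathepsin, astacin and Kunitz. With an estimated correlation adjusted p was 0.231 for trypsin, cathepsin and Kunitz and 0.261 for astacin, and with library totals alone it was 0.0816 for Kunitz.

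Cuticle and detoxification classes were called lower in the gland with camera's preset correlation. All 10 tested RR-type cuticle proteins, which carry a chitin-binding motif, fell, with a median log2 fold change of -6.15, or -5.22 with members at 0 set at their bound. A 271-residue member stood at 25.9 ± 6.53 CPM in body and 1.29 ± 0.937 in venom gland, or 0.761 without venom gland library 3. Cytochromes P450 had 3 of 44 higher and 35 lower, and a 489-residue P450 went the other way, at 31.2 ± 5.25 CPM in venom gland against 1.73 ± 0.633. Camera gave adjusted p = 3.79e-04 for cuticle and 5.05e-06 for P450, and an estimated correlation gave adjusted p = 0.201 and 0.231.

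Myosin, chaperone, tubulin and regulatory classes were called higher with camera's preset correlation. Myosin motors had 5 of 7 tested members higher and none lower, and a 1951-residue myosin stood at 14830 ± 619 CPM in venom gland against 1241 ± 298. A 376-residue actin stood at 48880 ± 6915 against 6818 ± 2706 CPM (log2 fold change 2.84, SE 0.40) and arginine kinase, which buffers ATP in arthropod muscle, at 5816 ± 1600 against 1131 ± 417. Of HSP70 chaperones 6 of 8 rose, of tubulins 8 of 14 rose and 2 fell, of homeodomain proteins 10 of 14 rose and 1 fell, of serine/threonine kinases 73 of 123 rose and 16 fell, and of EF-hand proteins, many of which bind calcium, 49 of 107 rose and 19 fell. A 426-residue homeodomain protein stood at 187.3 ± 8.30 CPM against 22.0 ± 5.02, a 451-residue tubulin at 484.6 ± 137 against 60.5 ± 12.8 and a 333-residue kinase at 653.7 ± 176 against 106.4 ± 33.0. Camera gave adjusted p = 0.0118 for myosin, 0.0413 for HSP70, 0.0426 for tubulin, 0.00666 for homeodomain, 3.87e-06 for kinase and 0.00405 for EF-hand classes, and an estimated correlation gave adjusted p = 0.231 for each. With library totals alone the numbers higher and lower were 3 and 1 for myosin, 3 and 2 for HSP70, 6 and 5 for tubulin, 8 and 3 for homeodomain, 46 and 34 for kinase and 30 and 44 for EF-hand classes. The EF-hand class was still called higher there, with a camera adjusted p of 0.00968, although more members were lower than higher, and adjusted p became 0.0718 for HSP70 and tubulin. HSP70 and tubulin also lost their calls without body library 1 (adjusted p = 0.0655 and 0.0520) and without body library 2 (0.0609 and 0.0634), and with complete frames only HSP70, myosin and tubulin had adjusted p = 0.242, 0.0658 and 0.0924.

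**Figure D1:**
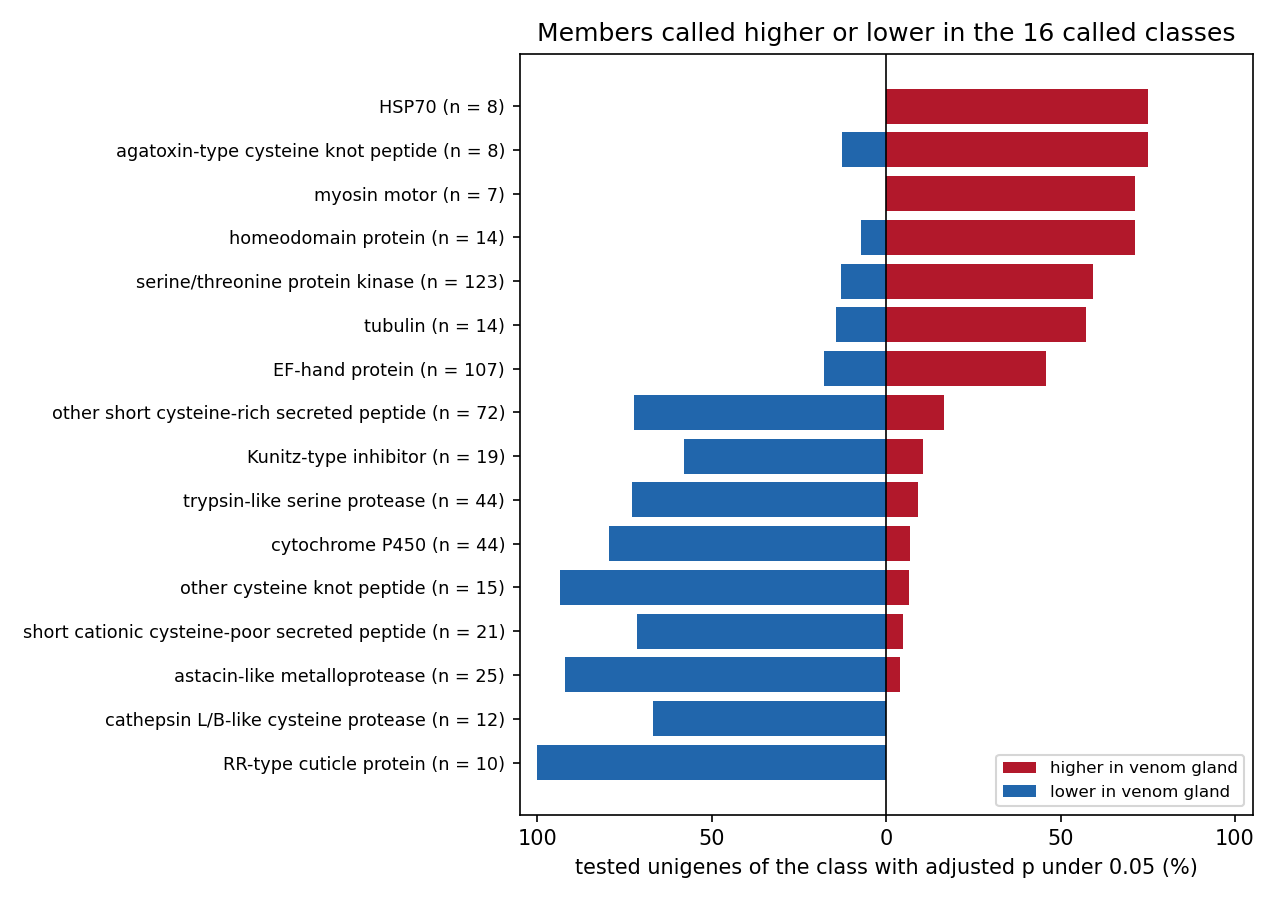
Share of tested unigenes in each of the 16 called classes that were higher (red, to the right) or lower (blue, to the left) in venom gland, in percent of the class on both sides of 0, with n the number tested. Agatoxin-type peptides have 6 of 8 members higher, while all 10 cuticle proteins are lower; with library totals alone 30 EF-hand proteins are higher and 44 lower.

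Among the 21 classes not called, proteins of the endoplasmic reticulum folding machinery came closest. Of these 12 of 24 rose and 3 fell, and a 495-residue protein of the disulfide isomerase type, which forms disulfide bonds in secreted proteins, stood at 25420 ± 3774 CPM against 2295 ± 170 (log2 fold change 3.47, SE 0.32). The class had a camera adjusted p of 0.0508, 0.0494 with the replicate number as a block and 0.0361 and 0.0179 without venom gland library 1 or 2, and 8 higher and 10 lower members with library totals alone. Neprilysin-like peptidases had 2 of 4 higher, with a camera adjusted p of 0.0656 and 0.0461 with the block. Camera with an estimated correlation called neither class, while fry called both, with adjusted p = 0.0217 for folding and 1.17e-04 for neprilysin-like proteins. CRISP proteins had 3 of 7 higher and 3 lower, angiotensin-converting enzyme-like peptidases 2 of 4 higher and 1 lower, phospholipases A2 1 of 14 higher and 7 lower, thyroglobulin type-1 proteins 1 of 9 higher and 6 lower, and serpins 2 of 13 higher and 8 lower. Lipases had 7 of 11 lower, chitinase-like enzymes 2 of 3, cyclophilins 3 of 9, histones 4 of 6 and ribosomal proteins 6 of 15, with none higher, and with library totals alone 7, 3, 7, 6 and 15 of them were lower. Rab-type GTPases had 13 of 35 higher and 7 lower, C2H2 zinc finger proteins 72 of 249 higher and 48 lower, ubiquitins 3 of 8 higher and 1 lower, and elongation GTPases 1 of 9 higher. With library totals alone the Rab, C2H2, ubiquitin and elongation counts turned to 8 and 17, 45 and 128, 1 and 4, and 0 and 5. Cys-loop channels had 4 of 12 higher and 2 lower, and 1 and 5 with library totals alone. G protein-coupled receptors had 6 of 21 higher and 8 lower, opsins 1 of 4 higher and 3 lower, actins 1 of 4 higher and 1 lower (3 lower with library totals alone), and hemocyanins 0 of 4 in either direction. For G protein-coupled receptors and hemocyanins the camera direction was up while the median log2 fold change was -0.94 and -0.24, and for CRISP the median was 0.37, or -0.66 with library totals alone.

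The other 9 classes held too few tested unigenes. Hyaluronidase, arginine kinase, tropomyosin and a Kazal-type protein had 1 tested member each, which rose. The tropomyosin call ended with library totals alone, at a log2 fold change of -0.01. Both spidroin-like unigenes fell, 1 of 2 HSP90 rose but not with library totals alone (edgeR, Benjamini-Hochberg adjusted p = 0.154), the single amylase had a log2 fold change of -0.39 without a call, the TCTP unigene was not tested, and no peptide matched the carboxylesterase pattern. Adjusted over the list alone, numbers differed from those above in 11 classes. They were 53 lower for other short cysteine-rich peptides, 1 lower for HSP90, 12 higher and 6 lower for Rab, 6 higher for myosin, 3 lower for tubulin, 0 lower for ubiquitin, 0 higher for elongation GTPases, 2 lower for ribosomal proteins, 70 higher and 42 lower for C2H2, 75 higher for kinases and 50 higher for EF-hand proteins.

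As a share of all counts, short cysteine-rich peptides made up much more of the gland than of the body. The 3 short cysteine-rich classes together took 12.7% ± 1.16 of venom gland counts and 1.903% ± 0.430 of body counts (SD, n = 3 each), a difference of 10.8 percentage points (exact two-sided permutation test, p = 0.10, the smallest that 3 against 3 allows). Agatoxin-type peptides took 4.38% ± 0.539 against 0.0540% ± 0.0136, other knot peptides 2.86% ± 0.623 against 0.0886% ± 0.0196, and other short cysteine-rich peptides 5.45% ± 0.194 against 1.76% ± 0.416. Trypsin-like proteases took 15.8% ± 2.501 against 0.337% ± 0.0672, almost all from the 281-residue protein. CRISP proteins took 1.07% ± 0.170 against 0.0112% ± 0.00212 and folding proteins 2.08% ± 0.349 against 0.634% ± 0.0635. The reverse held for cathepsins, with 0.0806% ± 0.0693 against 2.56% ± 1.15, astacins, with 0.00433% ± 0.00551 against 2.07% ± 0.402, P450, with 0.0169% ± 0.00209 against 0.476% ± 0.205, and spidroins, with 3.72e-05% ± 4.24e-05 against 0.251% ± 0.0276. Without venom gland library 1 the venom gland means were 0.0413% for cathepsins and 1.28e-05% for spidroins, and without venom gland library 3 that of astacins was 0.00117%. In each of these classes the 3 venom gland libraries lay on 1 side of the 3 body libraries, and each exact permutation p was 0.10. Shares did not always follow the class calls. Tubulins, called higher, took 0.230% ± 0.00340 against 0.376% ± 0.0633 (exact permutation p = 0.10). EF-hand proteins, also called higher, took 1.04% ± 0.0693 against 0.986% ± 0.168 (exact permutation p = 0.70). Reading frames open at the 5' end from a methionine, an alternative added after seeing the data, raised the difference for the 3 short cysteine-rich classes to 18.9 points.

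**Figure D2:**
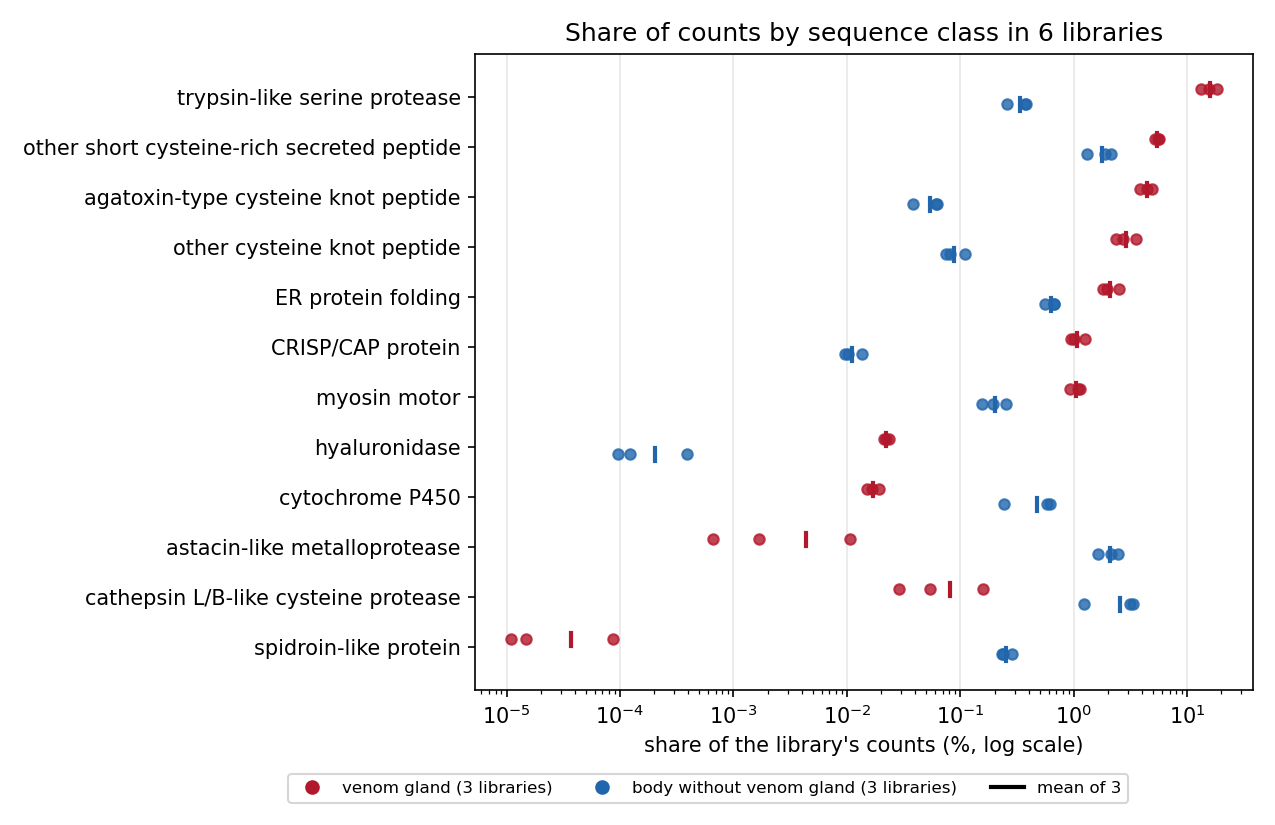
Share of each library's counts (percent, log scale) taken by 12 sequence classes, with a point per library (red venom gland, blue body without venom gland) and a bar at the mean of 3. Trypsin-like proteases average 15.8% in venom gland and 0.337% in body, and cytochromes P450 0.0169% and 0.476%.

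The gland's counts were also concentrated in fewer unigenes. The 20 most abundant unigenes, among them the 281-residue protease and the toxin-like peptides above, took 55.5% ± 0.965 of each venom gland library, and those of the body, among them the 7184-base unigene, virus-like unigenes and the cathepsin, 31.8% ± 10.8 (SD, n = 3 each; exact two-sided permutation test, p = 0.10). The difference was 23.7 percentage points, and 43.4 points in TPM. The value for body library 1 was 44.2%, against 27.3% and 24.0% for body libraries 2 and 3, and without it the difference was 29.9 points.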

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

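The alternatives were fixed before the data were examined, except those said below to have been added. Library totals alone gave 3179 unigenes higher and 10748 lower, against 5030 and 6750, and all 3179 were among those called with TMM factors. Only unigenes with a predicted reading frame, 10611 tested, gave 2957 higher and 3752 lower, of which 2939 and 3051 were shared with the main calls. The main fit had called 6443 unigenes with a predicted peptide, so the refit changed calls beyond testing fewer unigenes. The DESeq2 test, median-of-ratios factors, TMM factors without the 20 most abundant unigenes of each library, other filters, limma-voom, a 2-fold threshold and the replicate block gave 4422 to 6825 higher and 6054 to 8817 lower. DESeq2 left 59540 unigenes without an adjusted p. Leaving out 1 library gave 4618 to 6279 higher and 6014 to 7577 lower. With the replicate number as a block 5066 unigenes were higher and 6603 lower, of which 4871 and 6408 were shared with the unblocked calls. The block gave 9 classes higher and 9 lower, adding endoplasmic reticulum folding and neprilysin-like peptidases, ended 5 calls on named unigenes (adjusted p = 0.0513 to 0.0728, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and changed no other call on a named unigene or class. The counts were whole as deposited, so leaving them unrounded tested nothing.

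Camera called 7 classes higher and 9 lower. An estimated correlation left 0 higher and 0 lower, fry gave 15 higher and 16 lower, complete reading frames only gave 4 higher, and leaving out 1 library gave 5 to 8 higher. Fry tests each class on its own and does not compare it with other unigenes. For the 3 short cysteine-rich classes the difference in share was 10.8 points. It was 13.4 in TPM, 12.2 with peptides up to 200 residues and 18.9 with 5' open frames read from a methionine, an alternative added after seeing the data, and 10.4 to 11.4 with 1 library left out. For the 20 most abundant unigenes it was 23.7 points. It was 25.9 for the 100 most abundant, 43.4 in TPM, 19.8 to 29.9 with 1 library left out and, in alternatives added after seeing the data, 26.7 without virus-like unigenes and 29.3 without the most abundant unigene of body library 1. The cause of these moves was not tested.

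Over 83 named unigenes, 1240 values under alternatives kept direction and call in 1149 cases, lost the call in 86 and reversed in 5. With library totals alone the log2 fold change was -0.012 for a 319-residue phospholipase A2, -0.014 for tropomyosin and -0.35 for an elongation GTPase. Without body library 1 it was 4.15 for a 1074-residue virus-like unigene and 3.08 for a 419-residue unigene, whose counts lay almost wholly in that library, and other left-out libraries took them down to -12.90 and -12.98. Of the 83, 67 were called whichever library was left out and 14 lost the call at least once (adjusted p = 0.0506 to 0.155, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Without a low-count filter 11 calls were lost. Folds of unigenes without counts in a tissue are lower bounds only.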

Other observations

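All tests of explanations in this part were chosen after the results were seen. A 249-residue phospholipase A2 and a 136-residue histone had 0 venom gland counts against 65.4 ± 25.9 and 114.2 ± 18.0 CPM in body, at least 666-fold and 1201-fold lower, and at least 416.7-fold and 750.9-fold without venom gland library 2. A 401-residue opsin, a light receptor, had 165 venom gland counts and 0 in body, at 1.09, 11.19 and 2.15 CPM in the 3 venom gland libraries, while 3 other opsins fell. It was at least 112.5-fold higher, and at least 34.9-fold without venom gland library 2, 70.7-fold without body library 2 and 73.0-fold without body library 3. The call on the most abundant of those was lost without venom gland library 1 or 2 or body library 2 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0916, 0.0542 and 0.110) and with no low-count filter (0.349). A 2326-residue protein that matched the G protein-coupled receptor pattern stood at 190.5 ± 16.8 CPM in venom gland against 10.5 ± 4.79, and a 487-residue thyroglobulin type-1 protein at 7.31 ± 3.09 against 0.921 ± 0.460 (SD, n = 3 each). The receptor pattern matched 19 shuffled against 39 real peptides and the phospholipase A2 pattern 10 against 16, so both names may be chance matches. A 125-residue and a 119-residue frame open at the 5' end, which met the short cysteine-rich rules from an internal methionine, took 0.836% ± 0.218 and 1.65% ± 0.637 of venom gland counts.

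Unigenes with an RNA virus polymerase-like signature, added after the data were seen, made up 13.2%, 2.58% and 3.06% of counts in body libraries 1, 2 and 3, and 0.108%, 9.00e-04% and 0.00172% in the venom gland libraries. There were 6 with at least 10 raw CPM in a library. Proteins of 3359 and 3516 residues were high in all 3 body libraries, at 30000, 20260 and 11390 and at 11970, 5537 and 19190 raw CPM. A 1074-residue frame reached 89100 raw CPM in body library 1 and 6.11 and 3.35 in the others. A 3160-residue one stood at 750.7 raw CPM in body library 1 and 953.3 in venom gland library 1, and at 40.2 or less in the other libraries.

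The 1074-residue virus-like unigene of body library 1 was also counted in venom gland library 1, at 0.128% of its body level. Carry-over of body library 1 as a whole would put every abundant unigene at that share or above. Of 614 such unigenes 41 (6.68%) lay below it beyond Poisson error, 41 of the 173 whose expected counts were high enough to fall below, among them the 3359-residue virus-like unigene with 12 counts against 536.7 expected. This form replaced an earlier one whose outcome had been seen and decided nothing, in which 30 of 129 unigenes (23.3%) scarce in the other venom gland libraries reached that share. Libraries with the same number may share animals, since 12 of 12 other unigenes at least 20-fold higher in 1 body library than in either other, with at least 10 raw CPM there and 20 venom gland counts, had their highest venom gland level at the same number (chance 33.3%, one-sided exact binomial p = 1.88e-06), although unigenes are not independent, 1 of them (419 residues) followed the virus-like unigene, this count was known when the test was set, and a shared day or batch was not told apart.

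Venom gland library 3 held low levels of body transcripts, 0.241% of the body level against 0.0670% and 0.0385% in libraries 1 and 2, and was the highest of the 3 for 109 of 170 unigenes with at least 100 raw CPM in each body library and a venom gland median of at most 5. Carry-over of the same share of all body RNA would leave no unigene below that share. Of 34 unigenes able to fall below the median share of 0.114%, 5 did so beyond counting noise and the spread between body libraries. A spidroin-like unigene had 0 counts against 38.7 expected. The 5 unigenes below argue against a common share of all body RNA as high as this median, which came from the same unigenes. A smaller common share stays open, and for the other unigenes carry-over stays open too. Most of the 170 could not fall below, so the 2.94% that the 5 make of them decides nothing. Against the summed share 13 lay below and 20 above, and an earlier form seen first, with 166 unigenes limited in libraries 1 and 2 alone and a Poisson range that left out that spread, had 48.8% outside. Digestive tissue is a possible explanation that stays open, since the median of 9 unigenes of digestive enzyme classes, picked after such traces were seen, exceeded that of 161 others by 0.260 percentage points of the body level (0.372 against 0.112, permutation p = 0.0769). Limits of 2 and 10 raw CPM gave 4 of 146 and 7 of 196 unigenes below, 2.74% and 3.57% of all selected, able to fall below or not. The differences were 0.0235 and 0.223 points (permutation p = 0.654 and 0.307), and all of these forms were chosen after outcomes had been seen.

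Of 13 tested unigenes of the myosin, actin, tropomyosin and arginine kinase classes 8 were higher in the gland, 1 actin was lower and 4 were not called, although the lower actin lost its call with the replicate block (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0553), without venom gland library 1, 2 or 3 (0.110, 0.0720 and 0.111) and without body library 2 (0.0983). Composition scaling alone does not account for the 8, since 5 of them kept their call with library totals alone, but for the other 3 it stays open. A larger share of 1 kind of muscle stays open too. Log2 fold changes ranged over 5.17 across the 13, from -0.88 to 4.30, and over 3.27 across the 8, but actin and myosin also occur outside muscle and no unigene is known to be of muscle alone, so neither range decides. Muscle of another makeup around or in the gland may be a source, which was not tested.

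The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 5030 unigenes higher and 6750 lower, 1 of 10 splits in each case, and the highest of the others gave 0. For classes the real split gave 7 higher and 9 lower, and 5 and 2 of the 10 splits gave as many in a direction, the highest of the others being 9 in both cases. The number of classes called therefore did not set the real split apart. Same-numbered libraries deviated together, and 4 of the 10 splits part all 3 pairs, the real one included. Among these 4 the highest of the others gave 0 unigenes and 9 classes, and among the other 6 the highest gave 0 and 7.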
